A study of Mus musculus with 4 samples.

How the data were processed

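Haematopoietic stem cells (HSCs) were taken from the bone marrow of mice that carry N-myc fused to the red fluorescent protein mCherry. Per the labels' protocols, cells that lacked lineage markers and CD48 and carried Sca-1, Kit and CD150 were collected straight into Trizol without culture or treatment. mCherry served to part them into an N-myc high and an N-myc low fraction. Each fraction was profiled from samples labelled mouse 1 and mouse 2, which gives 4 arrays, 2 per group. Per the labels' protocols, 5 ng of total RNA was amplified and biotin-labelled with the NuGEN Ovation reagents and hybridised to an Affymetrix mouse array. Such an amplification starts from little RNA, and unequal amplification adds spread between arrays, most of all for dim transcripts.

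The deposited values are log2 probe set intensities on which the authors ran RMA, per the submitters' processing notes, which also name affy and limma without versions. RMA corrects background, normalises probes by quantiles and sums up each probe set, so a shift shared by all genes of an array is removed and the values hold no absolute RNA amount. The genome build, the chip definition and any filter are not given in the sources used here. Detection calls were not used here, so a dim value has no measured background beside it, and the number of arrays limits the precision. The 4 arrays had median log2 intensities of 5.26 and 5.28 (N-myc high, mouse 1 and 2) and 5.32 and 5.27 (N-myc low, mouse 1 and 2).

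Of 45101 probe sets, 64 were control probe sets, 34945 carried 1 gene name in the platform annotation, 932 carried several and 9160 were unnamed here. For 34741 of the probe sets with 1 gene name, the Entrez number was found in a RefSeq gene table (assembly GRCm38.p6, used for names alone), and 0 symbols changed. Probe sets with several names and unnamed ones entered no gene-level test. For each of 18193 genes, the probe set with the highest mean over the 4 arrays stood for the gene, and 9010 genes had more than 1 probe set. No filter was put on dim genes.

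The groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with the default prior), and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. A descriptive count took genes at an unadjusted p under 0.01 and at least 1.5-fold. Standard errors (SE) are those of the moderated limma fit. With 2 against 2 arrays, an exact permutation test of a single value cannot go below a two-sided p of 0.333, since the arrays make 3 splits, so limma's pooled spread carries every p printed here. The self-test drew values for the 18193 genes with 200 changed, in 20 simulations. It recovered 0% of genes changed by 1 on the log2 scale at the adjusted threshold, 6.19% of those changed by 2 and 55.4% of those changed by 3, with 2.05 false calls per simulation.

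A set of 26 gene lists was fixed before the data were examined, together with the test, the alternatives and the rule for named genes. The lists held 828 distinct genes, of which 735 were measured and 93 were not. Each list was tested with camera in limma, which compares its members with all other genes at a preset correlation of 0.01, and p values were adjusted over the 26 lists. camera with an estimated correlation and fry, which asks whether the members move one way without reference to other genes, stood beside it. In the self-test, a list shifted by 0.4 on the log2 scale was called by camera in 100% of simulations, by fry in 15% and with an estimated correlation in 0%. The simulated genes were independent of each other, so these shares say nothing about lists whose genes vary together. The estimated correlation rests on 2 residual degrees of freedom.

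The named genes were Mycn and Huwe1 whatever their values, then in each direction the 15 genes with the largest difference past the adjusted threshold and the same sign in both mice. Where fewer than 15 passed, places were filled by the smallest unadjusted p among genes that differed by at least 1 on the log2 scale, again with the same sign in both mice. From each list the 4 members with the smallest unadjusted p were named. Genes named outside this rule were chosen after their values were seen, namely Flt3 as a progenitor gene, Xist, Eif2s3y and Kdm5d, C1qa and C1qc, Cd79b, Ighm, Itgax and Siglech, Igll1, H2-DMa and Ciita, and the genes that compare mouse 1 with mouse 2.

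The labels name the mouse of each array, and arrays with the same number were read as coming from the same animal. Xist fitted this pairing, with 11.4 and 11.1 in the N-myc high and low arrays of mouse 1 and 3.84 and 3.70 in those of mouse 2. Both arrays of mouse 1 also carried the Y-linked Eif2s3y at 8.53 and 8.43, so it is open whether they hold RNA of a single animal or of a pool or mixture, and a difference within mouse 1 is one within whatever that sample holds. Across genes, the deviations of same-numbered arrays from their group means correlated at r = 0.0492. The fit without the mouse was the main one, since the processing notes name no pairing, and the mouse as a replicate block was an alternative.

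The other alternatives fixed in advance were median centring of each array, cyclic loess, the mean of all probe sets of a gene, a filter that left out the dimmer 50% of genes, a test of every probe set, adjusted p under 0.1, a minimum log2 difference of 1, a trended and robust prior, camera on ranks, and leaving out each array in turn. Lists without Mycn and the surface genes of the sort, lists without genes shared with another list, the mean of the bioB and bioC hybridisation controls as a covariate, and camera with an estimated correlation while each array was left out were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.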

Results

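The series, which centres on the ubiquitin ligase Huwe1 in blood stem cells, asks here how HSCs with high and low levels of the transcription factor N-myc differ in gene expression. RNA of N-myc high and N-myc low HSCs was measured on 4 arrays, with each fraction from samples labelled mouse 1 and mouse 2. At the gene level the N-myc high arrays correlated at r = 0.980, the N-myc low arrays at 0.972, and the fractions of mouse 1 and of mouse 2 at 0.977 and 0.972. The ratio of 3' to 5' signal for Gapdh, a sign of RNA integrity, was 1.43 and 1.5 on the log2 scale in N-myc high and 1.40 and 1.62 in N-myc low. The same ratio for actin was -0.19 and -0.09 in N-myc high and -0.28 and -0.19 in N-myc low.

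N-myc high HSCs had higher levels of genes typical of long-term HSCs, among them Procr, Cdkn1c and Fgd5, and lower levels of multipotent progenitor genes, among them Cd48 and Cdk6. Genes of quiescence and of the interferon response were higher as groups, and granulocyte and monocyte genes were lower. The list with MHC class II genes, led by Cd74 and H2-Aa, was called higher, while the lists of ribosome and cell cycle genes were not called and had medians between -0.06 and 0.01. These list calls were made by camera at its preset correlation, and each was lost with an estimated correlation (adjusted p = 0.447 to 0.479). That variant rests on 2 residual degrees of freedom and called a simulated list of independent genes shifted by 0.4 in 0% of simulations. Its loss therefore cannot tell an absent shift from a missed one. With fry, 2 lists were called, long-term HSC genes and the list with MHC class II genes. It called the simulated list in 15% of simulations. The camera test that called 6 lists here called 8 when the arrays were split by mouse in place of N-myc level. No single gene passed the adjusted threshold in limma, so the differences of single genes, those of Procr, Cdkn1c and Fgd5 included, are values that missed it.

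Mycn, the gene behind the sort, had a log2 intensity of 10.43 ± 0.069 (SD, n = 2) in N-myc high and 9.54 ± 0.15 (SD, n = 2) in N-myc low HSCs, a 1.85-fold difference. The difference was 0.89 with an SE of 0.189 (limma adjusted p = 0.762), and it was 1.05 in mouse 1 and 0.74 in mouse 2. The other probe sets of Mycn gave 0.11 and 1.06, and neither was higher in both mice. The 1.06 came from mouse 2 alone (6.72 in N-myc high and 4.40 in N-myc low), with 4.32 and 4.52 in mouse 1. Whether the Mycn probe sets also read the fusion transcript was not determined here. Huwe1, the ubiquitin ligase of the series title, was at 9.80 ± 0.059 (SD, n = 2) in N-myc high and 9.92 ± 0.043 (SD, n = 2) in N-myc low HSCs. Its difference of -0.12 was smaller than its SE of 0.175 (limma adjusted p = 0.920). The other probe sets of Huwe1 gave -0.59, -0.12, 0.44 and -0.15, so the sign depended on the probe set.

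Of 18193 genes, 0 passed an adjusted p under 0.05 in limma, and the lowest adjusted p was 0.671. At an unadjusted p under 0.05 there were 1148 genes, where chance gives 910. At an unadjusted p under 0.01 and 1.5-fold there were 223 genes, 135 higher and 88 lower in N-myc high, where chance gives 182 at that p. Both N-myc high arrays lay above both N-myc low arrays for 2836 genes (15.6%) and below them for 3789 (20.8%), where chance gives 16.7% each. Across genes, which are not independent replicates, the difference in mouse 1 correlated with that in mouse 2 at r = 0.110, and 53% of genes had the same sign. With the mice crossed r was 0.0616, and between mice within a fraction it was 0.0492. The excess of 223 over chance was not stable. With the mouse as a replicate block the count was 173, fewer than the 182 that chance gives at that p. It was 107 without the dimmer genes and 557 over every probe set, where fewer and more features were tested. The majority direction was not stable, since 267 of those 557 probe sets, 154 of 319 genes without N-myc low mouse 1, 118 of 242 without N-myc low mouse 2 and 137 of 281 with the hybridisation controls as a covariate were higher, against 129 of 173 with the mouse as a replicate block.

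The 15 genes taken by smallest p on the higher side all missed the adjusted threshold. C1qb, a chain of complement C1q, was higher by 2.66 on the log2 scale (SE 0.194), and the imprinted noncoding RNA Meg3 by 2.94 (SE 0.274). Cd74, the invariant chain of MHC class II, was higher by 2.15 (SE 0.217) and H2-Aa, an MHC class II alpha chain, by 1.42 (SE 0.176). The cyclic nucleotide phosphodiesterases Pde2a and Pde1b were higher by 2.26 and 1.99, the actin nucleator Fmn2 by 2.48, the inhibitory G protein subunit Gnai1 by 1.94, the planar polarity gene Prickle1 by 1.61 and the endothelial surface gene Ecscr by 1.52. The others were Clip3 (2.47), Kazald1 (2.38), Ankrd63 (2.10), Thnsl1 (1.95) and Gpr19 (1.61).

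On the lower side, the 15 genes likewise missed the threshold. Pfn2, a profilin that binds actin, was lower with a log2 difference of -3.81 (SE 0.315), and Cd48, a surface protein that the sort selects against, with -2.21 (SE 0.340). Cd69, an early activation antigen of leukocytes, gave -1.42, the fatty acid receptor gene Ffar2 -2.45, the Wnt ligand gene Wnt2b -2.28, Oasl1, of the oligoadenylate synthetase-like family, -1.68, and Rad51ap1, of homologous recombination, -1.48. The others were Sgip1 (-2.12), Btnl9 (-1.78), Slfn10-ps (-1.77), Uxt (-1.38), Nlrc3 (-1.32), Psd3 (-1.23), Marchf1, a membrane ubiquitin ligase of MHC class II (-1.14), and Nadk2 (-1.05). Of the 30 genes, 14 had their lower group mean in the dimmer 50% of all values, 11 rested on 1 probe set and 7 had another probe set of opposite sign. Pde2a gave 0.11 and 0.16, and Pfn2 0.05 and -0.60, with their other probe sets. Of the 11 probe sets of Meg3, 3 had the opposite sign, and those besides the one used ranged from -0.48 to 2.58.

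**Figure D1:**
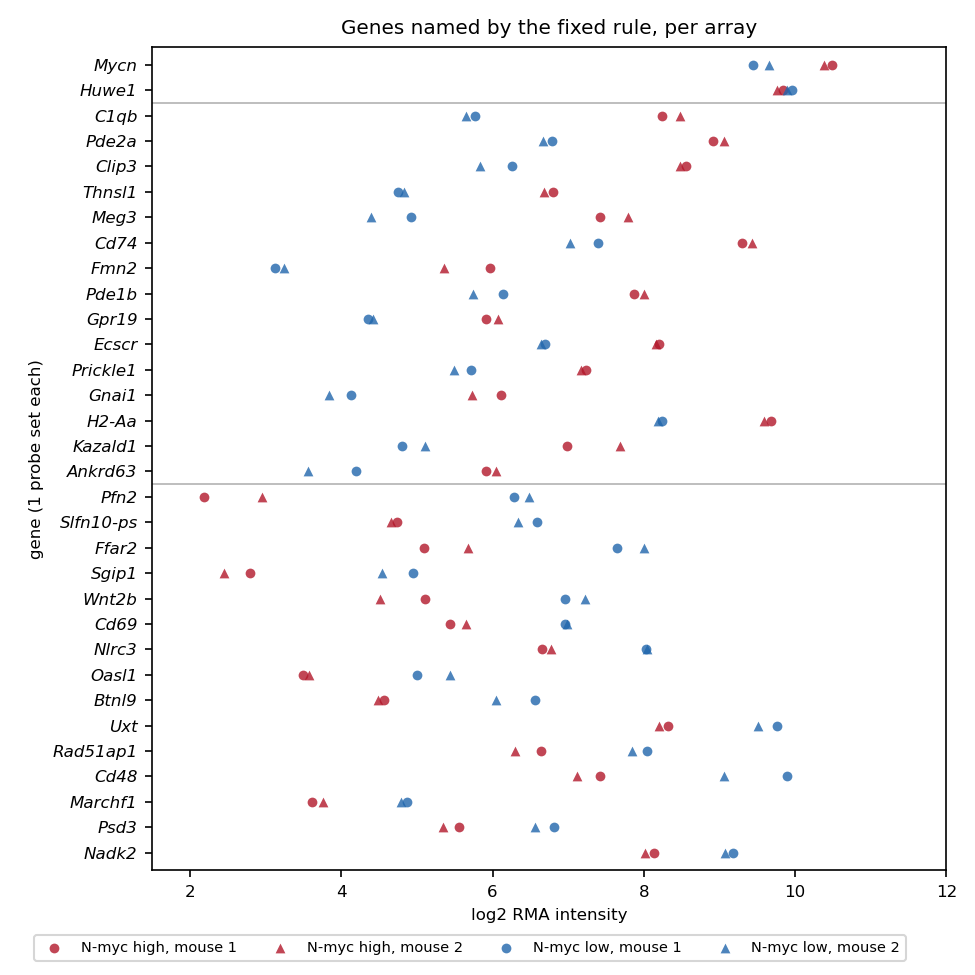
Log2 RMA intensity (horizontal axis) of Mycn, Huwe1 and the 15 genes of smallest p in each direction, 1 point per array, with circles for mouse 1 and triangles for mouse 2. Mycn lies at 10.43 on average in N-myc high and 9.54 in N-myc low HSCs, and none of these genes passed the adjusted threshold.

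Long-term HSC genes were higher as a group in N-myc high HSCs (camera adjusted p = 1.5e-08 in limma; adjusted p = 0.447 with an estimated correlation). The 40 measured members had a median difference of 0.42, with 0.19 in mouse 1 and 0.52 in mouse 2, and 22 were higher and 5 lower in both mice. At an unadjusted p under 0.05, 14 were higher and 0 lower, while 0 passed over all genes and 0 adjusted over the list alone. Procr, the endothelial protein C receptor, was higher by 1.19 (SE 0.177), Fgd5, an HSC marker gene, by 1.58 (SE 0.330), and Cdkn1c, a cyclin-dependent kinase inhibitor, by 1.69 (SE 0.325). Mycn itself belongs to this list. With Mycn and the surface genes of the sort taken out of the lists, camera called 6 lists, as many as with them. The bioB and bioC hybridisation controls, added to every sample before hybridisation, were at 10.85 and 10.81 in N-myc high and 11.05 and 11.67 in N-myc low (mouse 1 and 2). The median of the list was 0.24 with these controls as a covariate and 0.24 without N-myc low mouse 2, and the camera call stood in both.

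Multipotent progenitor genes were lower as a group (camera adjusted p = 0.00013 in limma; adjusted p = 0.447 with an estimated correlation). The median difference of the 19 measured members was -0.51, 15 were lower and 2 higher in both mice, and 0 passed over all genes and 2 adjusted over the list alone. After Cd48 (-2.21), the members of smallest p were Cdk6, a kinase of G1 progression, with -0.97 (SE 0.189), Plac8 with -0.85 and the cytotoxic granule gene Nkg7 with -0.77. Flt3, a receptor of multipotent and lymphoid progenitors, went the other way with 1.20 (SE 0.355). The call was lost with fry (adjusted p = 0.144).

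Genes of quiescence and cell-cycle restraint were higher as a group (camera adjusted p = 0.0015 in limma; adjusted p = 0.447 with an estimated correlation). The median over 33 members was 0.26, 18 were higher and 4 lower in both mice, and 0 passed adjusted over the list alone. Besides Cdkn1c, Ski, a repressor of TGF-beta signalling, was higher by 1.01 (SE 0.351), the retinoblastoma family gene Rbl2 by 0.70 (SE 0.251), and the TGF-beta receptor gene Tgfbr2 by 0.63 (SE 0.202), although Tgfbr2 was -0.043 over the mean of its probe sets. The call was lost with that mean (adjusted p = 0.0618, median 0.12) and with fry (adjusted p = 0.289).

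Interferon response genes were higher as a group (camera adjusted p = 0.00060 in limma; adjusted p = 0.479 with an estimated correlation), with a median of 0.27 over 31 members, 18 higher and 2 lower in both mice. The interferon-induced GTPase genes Iigp1 and Igtp were higher by 1.76 (SE 0.653) and 0.92 (SE 0.300). The antiviral genes Rsad2 and Ifit2 were higher by 0.73 and 0.50. Oasl1, which is not in the list although genes of its family are, went the other way with -1.68 (SE 0.225). Adjusted over the list alone, 0 passed. The call was lost with fry (adjusted p = 0.446), without N-myc high mouse 1 (adjusted p = 0.129, median 0.16) and with the hybridisation controls as a covariate (adjusted p = 0.114, median 0.31).

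The list of dendritic cell and MHC class II genes was called higher (camera adjusted p = 0.0173 in limma; adjusted p = 0.479 with an estimated correlation), although the median over its 18 members was -0.01 and the mean 0.40. This median was 0.15 and 0.09 without N-myc high mouse 1 and 2, and 0.01 and 0.15 without N-myc low mouse 1 and 2. The 6 MHC class II genes, set apart after their values were seen, had a median of 0.94, with 4 higher in both mice, H2-DMa at -0.12 and Ciita at 0.11 with opposite signs in the mice, and the other 12 members had a median of -0.04. Adjusted over the list alone, 4 passed. Besides Cd74 and H2-Aa, the members of smallest p were the MHC class II beta chain gene H2-Eb1, higher by 1.14 (SE 0.245), and the transcription factor gene Zbtb46, higher by 1.64 (SE 0.226), although its other 3 probe sets had the opposite sign. With fry the adjusted p was 0.0402, and 0.214 with the mouse as a replicate block, which ended the fry call. The camera call was lost on ranks (adjusted p = 0.267), without N-myc high mouse 1 (adjusted p = 0.129) and without N-myc low mouse 1 (adjusted p = 0.0961).

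Granulocyte and monocyte genes were lower as a group (camera adjusted p = 0.0350 in limma; adjusted p = 0.479 with an estimated correlation), with a median of -0.28 over 32 members, 18 lower and 7 higher in both mice, and 0 passed adjusted over the list alone. The granule protein genes Mpo and Elane gave -0.63 (SE 0.192) and -0.83 (SE 0.341) and the Fc receptor gene Fcgr3 -0.75, while the transcription factor gene Cebpd gave 0.47. The call was lost with fry (adjusted p = 0.289), with the mean of probe sets (0.0927), without N-myc high mouse 2 (0.291, with the median at -0.16), without N-myc low mouse 1 (0.152, with the median at -0.16), with the covariate (0.102) and without genes shared with another list (0.186).

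**Figure D2:**
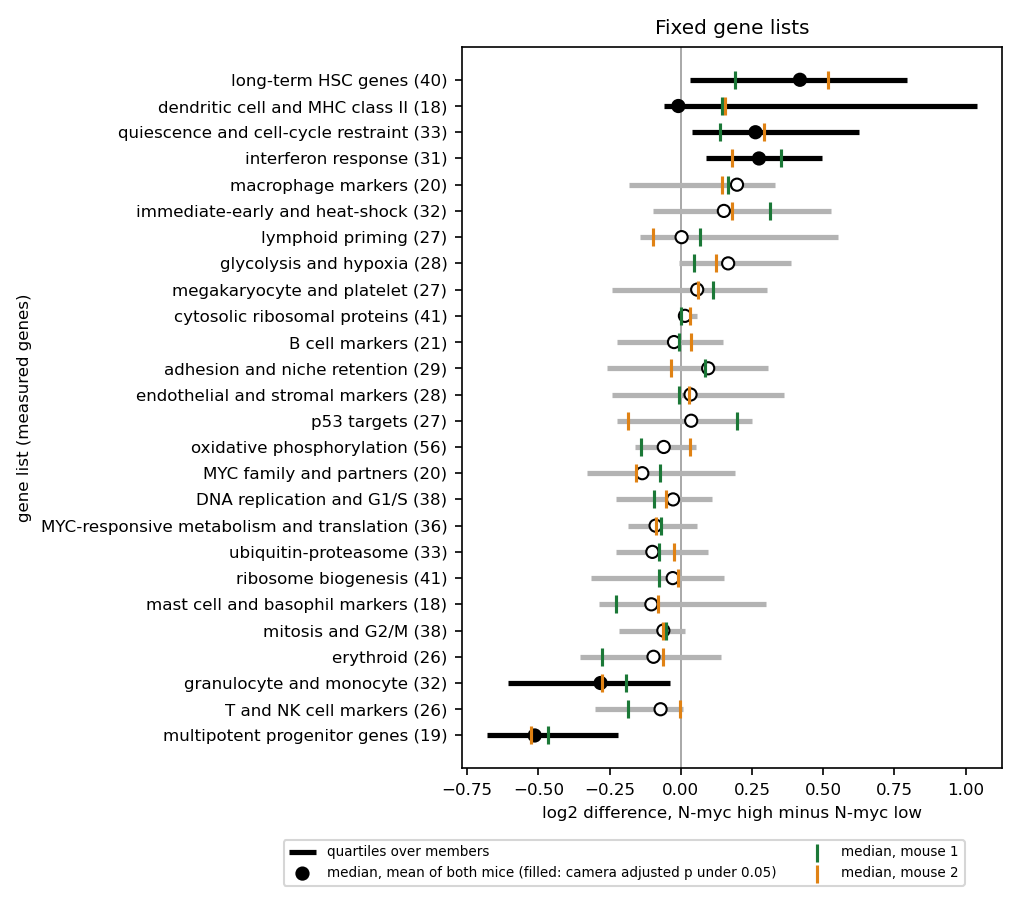
Median log2 difference (N-myc high minus N-myc low, horizontal axis) of each fixed gene list with the quartiles of its members as bars, and ticks for the medians of mouse 1 and mouse 2. Filled points are the 6 lists called by camera, with long-term HSC genes at 0.42 and multipotent progenitor genes at -0.51.

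The other 20 lists were not called. Of the 99 genes named from all lists, 20 had another probe set of opposite sign. Among the groups tied to MYC function, ribosome biogenesis had a median of -0.03 over 41 members (Rrp12 -0.85, Bop1 -0.69, Ltv1 -0.60, Ppan -0.46). Cytosolic ribosomal proteins had 0.01 over the 41 measured of 73 entries (Rps25 0.74, Rps6 0.59, Rpl14 0.23, Rps16 0.18). Rps25 was -0.09 without N-myc low mouse 2, and Rps16 lay at a dim 2.73 in N-myc high and 2.55 in N-myc low. MYC-responsive metabolism and translation had -0.09 (Eif3b 0.53, Gart -0.45, Shmt1 -0.36, Atic -0.29). MYC family and partners had a median of -0.14 (Mxd4 -0.66, Mlx -0.55, Wdr5 0.46), although Wdr5 was -0.028 over the mean of its probe sets. Ubiquitin-proteasome genes had -0.10 (Psmd13 -1.06, Psmd14 0.68, Psmc2 -0.58, Psmd7 -0.39). Genes of DNA replication and G1/S were at -0.03 (Rfc4 -0.71, Pole -0.51, Tyms 0.45, Lig1 -0.40) and those of mitosis and G2/M at -0.06 (Bub1 -1.02, Hmmr 0.68, Anln -0.60, Birc5 -0.48). p53 targets were at 0.04 (Perp -1.04, Polk 0.70, Aen -0.67, Bbc3 -0.45), oxidative phosphorylation at -0.06 (Ndufa1 -0.61, Ndufs8 -0.56, Sdhb 0.52, Uqcrfs1 0.37), and glycolysis and hypoxia at 0.17 (Hk2 0.70, Egln1 0.56, Pfkl 0.49, Aldoc 0.38).

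Among lineage lists, lymphoid priming had a median of 0.00 (Cnn3 1.47, Flt3 1.20, Ets1 0.80, Ikzf1 -0.52), megakaryocyte and platelet genes 0.06 (Vwf 1.88, Gp1bb -1.0, Mmrn1 0.90, Gata1 -0.80) and erythroid genes -0.10 (Klf1 -0.93, Gata1 -0.80, Slc4a1 -0.68, Rhag 0.63). Macrophage markers were at 0.20 (C1qb 2.66, Mrc1 2.26, Axl 0.39, Siglec1 -0.36), with 1 gene, C1qb, passing adjusted over the list alone. B cell markers were at -0.02 (Vpreb1 2.45, Cd79a 0.65, Blk -0.52, Spib -0.39), T and NK cell markers at -0.07 (Ccl5 -1.37, Gzmb -0.87, Nkg7 -0.77, Prf1 -0.64), and mast cell and basophil markers at -0.10 (Cpa3 -1.59, Gzmb -0.87, Ccl4 0.56, Tpsab1 -0.39). Endothelial and stromal markers were at 0.03 (Stab1 -1.31, Ramp2 0.93, Emcn 0.60, Bgn 0.54) and adhesion and niche retention genes at 0.10 (Alcam 0.77, Itgal -0.73, Itgb7 -0.64, Icam2 -0.63). Immediate-early and heat-shock genes had a median of 0.15 (Klf4 0.83, Maff 0.83, Dusp2 0.78, Jund 0.60), and their camera adjusted p was 0.0618 (adjusted p = 0.834 with an estimated correlation), and 0.0101 with the mouse as a replicate block, which called them higher. In that blocked fit the call was lost with an estimated correlation (adjusted p = 0.795) and with fry (adjusted p = 0.214).

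In all, camera called 6 of the 26 lists, 4 higher and 2 lower, against 0 with an estimated correlation and 2 with fry, long-term HSC genes and the list with MHC class II genes. The same camera test called 8 lists when the arrays were split by mouse in place of N-myc level and 0 when they were split across both. Leaving out 1 array gave 8 further calls over 6 lists at the preset correlation, but it also unbalances the mice, and all 8 had the sign that the difference between mouse 1 and mouse 2 gives. With an estimated correlation, 0 lists were called with an array left out, and the smallest adjusted p among these 8 was 0.710. The shared sign of the further calls was partly fixed in advance. Leaving out an array moves the difference by part of the difference between the mice in these same arrays. That sign therefore does not show what made those calls. The medians moved with the array left out. Macrophage markers were at 0.31 without N-myc high mouse 2 and -0.09 without N-myc high mouse 1. Immediate-early genes were at 0.53 without N-myc low mouse 2 and -0.11 without N-myc low mouse 1. Erythroid genes were at -0.30 and 0.10, and oxidative phosphorylation genes at -0.17 and 0.04, without the same pair of N-myc low arrays.

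**Figure D3:**
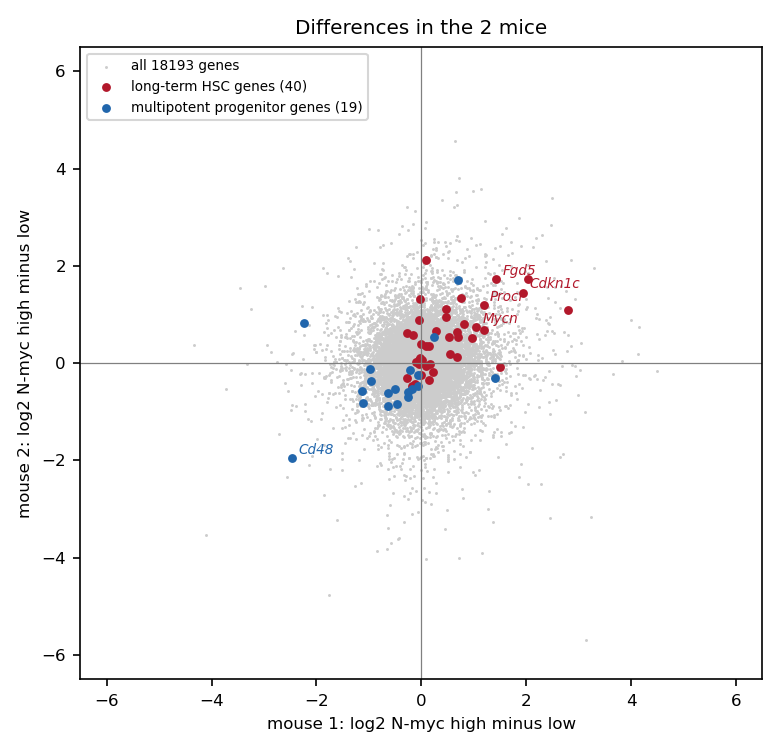
Log2 difference (N-myc high minus N-myc low) of each gene in mouse 1 (horizontal axis) and mouse 2 (vertical axis), with grey points for all 18193 genes, red for the 40 long-term HSC genes and blue for the 19 multipotent progenitor genes. Across all genes r was 0.110, while 22 of the long-term HSC genes lie above 0 and 15 of the progenitor genes below 0 in both mice.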

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

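All tests in this part were chosen after the results were seen, and the rules for the progenitor, macrophage, B cell and dendritic cell tests were changed after the outcome of earlier rules was known; those for the last 3 had counted against these sources. The bioB and bioC hybridisation controls, which lie outside the gene comparison, stood 0.770 higher on the log2 scale in N-myc low mouse 2 than the mean of the other arrays, whose own range was 0.238.

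Long-term HSC genes were higher and multipotent progenitor genes lower in N-myc high HSCs by camera at its preset correlation (adjusted p = 0.447 for each with an estimated correlation). At that preset, with the hybridisation controls as a covariate, both lists still passed (adjusted p = 0.00051 and 0.00176). The median of the HSC list was 0.24 in that fit and 0.42 without it. The controls were higher in both N-myc low arrays than in the N-myc high arrays. With 4 arrays, this fit therefore cannot separate labelled material or hybridisation from N-myc level, and that cause stays open. A share of CD48-positive progenitors in the N-myc low sort would also raise myeloid and erythroid genes there. Without genes shared with another list, neither the granulocyte and monocyte nor the erythroid list was called by camera (adjusted p = 0.186 and 0.588). Such a share stays open, since the removed genes include Mpo (-0.63). The full granulocyte and monocyte list was called lower (camera adjusted p = 0.0350), and the full erythroid list was not called (0.452). Cd48, which the sort selects against, differed by -2.21. Flt3, a receptor of multipotent and lymphoid progenitors, went the other way (1.20). Whether progenitors within this CD150 gate would carry Flt3 was not tested, so Flt3 does not count against such a share. The erythroid genes Klf1 (-0.93) and Gata1 (-0.80) were lower in N-myc high, and 11 genes of that list were lower and 5 higher in both mice. A state of the stem cells that goes with N-myc level may account for the pattern and stays a hypothesis, as does a different mix of cells within the gate.

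C1qb led the genes higher in N-myc high by p. Macrophages, which the gate should remove, would bring the partner chains along, yet C1qa was higher by 0.32 (SE 0.428) and C1qc by 0.26 (SE 0.401), and the larger of both plus 2 SE was 1.17, which lies under the 2 probe sets of C1qb marked for possible cross-hybridisation but not under the unmarked one. Over the 20 genes of the fixed macrophage list the median was 0.20, with 8 higher and 3 lower in both mice, and Mrc1 was higher by 0.73 in mouse 1 and 3.80 in mouse 2, so macrophage RNA stays open. Another transcript read by the marked probe sets stays open, since the unmarked one differed by 0.99 (SE 0.467), neither near 0 nor near 2.66. No biological explanation was tested.

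The 6 MHC class II genes, set apart after their values were seen and not tested as a set, had a median of 0.94 from 2.15 for Cd74 to -0.12 for H2-DMa, and the call of their whole list was lost with an estimated correlation (adjusted p = 0.479). For RNA of B cells, Vpreb1 plus 2 SE reached 4.09, but Vpreb1 was higher by 4.16 in mouse 1 and 0.75 in mouse 2, and Ighm gave 3.23 and -3.17, whereas Cd74 was higher by 1.90 and 2.41. Cd79a, at a dim 4.50, was higher by 0.71 and 0.60 and Igll1 by 0.12 in each mouse, while Cd79b differed by -0.21 (SE 0.395), so B cell RNA is not excluded. For RNA of dendritic cells, Flt3, which progenitors also express, plus 2 SE reached 1.91, while Zbtb46 (1.64) rests on a probe set whose 3 companions have the opposite sign, and Itgax (0.01) and Siglech (-0.05) did not differ by more than their SE. Both stay open although the gate should remove these cells, and HSCs may express these genes themselves, which was not tested.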

How the results depend on the processing

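The tests with the lists without sort genes, the lists without shared genes, the covariate and an estimated correlation with each array left out (0 lists called) were chosen after seeing the data. The count of genes past the adjusted threshold was 0 under every alternative that gave one, leaving out each array included, where the lone array is assumed to vary like the other group; 1148 genes had an unadjusted p under 0.05. With the replicate block it was 0, the descriptive count was 173, where chance gives 182 at that p, and 7 lists were called. Immediate-early genes were the only change among the camera calls. With the block, fry lost the list with MHC class II genes (adjusted p = 0.214) and kept long-term HSC genes (0.000101). The count of 223 was 107 without the dimmer 50% of genes (fewer genes tested), 557 over every probe set (more features tested) and 117 to 319 with each array left out. The count of 6 lists was 0 with an estimated correlation, 2 with fry and 5 to 10 with each array left out, the highest without N-myc low mouse 2. It was 8 with the hybridisation covariate, which newly called erythroid (adjusted p = 0.0057) and oxidative phosphorylation genes (0.0147) lower and lymphoid priming (0.0250) and immediate-early genes (0.00011) higher. The mean of probe sets newly called glycolysis and hypoxia (0.0168) and immediate-early genes (0.0064) higher. These calls were made at the preset correlation. Of 414 list values under alternatives, 378 kept their call, 21 lost it, 15 gained one and 0 reversed; 12 of the 20 uncalled lists had the other sign at least once. Of 1227 gene values, 1224 kept their sign. Wdr5 was -0.028 and Tgfbr2 -0.043 over the mean of probe sets, and Rps25 ranged from -0.0903 to 1.56 with each array left out. Where no construction is named, the cause was not tested. Dim genes have no measured background here, which limits 14 of the 30 named genes and dim list genes such as Rps16, Spib and Tpsab1.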

Other observations

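All tests in this part were chosen after the results were seen. The 2 arrays of each mouse number are its 2 fractions, so the comparison sets 1 mouse number against 1. Its p values measure spread between fractions and not between animals. Immediate-early and heat-shock genes differed between mouse 1 and mouse 2 in both fractions. The 32 members had a median of -0.62 in mouse 1 minus mouse 2, with -0.65 in N-myc high and -0.59 in N-myc low HSCs, and 22 were lower in mouse 1 in both fractions (camera adjusted p = 8.3e-10 in limma; adjusted p = 0.621 with an estimated correlation and 0.448 with fry). The heat-shock genes Hspa1b and Hspa1a gave -2.36 (SE 0.325) and -1.90 (SE 0.283), and the AP-1 genes Fosb and Jun -1.37 (SE 0.305) and -0.89 (SE 0.190).

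Erythroid genes, macrophage markers and oxidative phosphorylation genes were higher as groups in mouse 1 (camera adjusted p = 0.00327 for each in limma; adjusted p = 0.621, 0.621 and 0.642 with an estimated correlation), with medians of 0.19, 0.25 and 0.12. Their medians were 0.08, 0.04 and 0.07 between the N-myc high arrays and 0.29, 0.26 and 0.21 between the N-myc low arrays, one of which has the outlying hybridisation controls. Xist was 11.4 and 11.1 in the arrays of mouse 1, yet the Y-linked genes Eif2s3y and Kdm5d were at 8.53 and 6.51 in its N-myc high and 8.43 and 7.36 in its N-myc low array. In mouse 2, with Xist at 3.84 and 3.70, Eif2s3y was at 9.40 and 9.67 and Kdm5d at 8.36 and 7.91. Whether the arrays of mouse 1 hold RNA of a single animal is open, and so is whether the differences between the mice above are differences between 2 animals.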
